A study of Bacillus subtilis with 13 samples.

How the data were processed

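RNA sequencing counts were used from 13 libraries labelled Bacillus subtilis strain PY79, grown as biofilm colonies for 24 hours on MSgg solid medium. Per the labels' protocols, 3 colonies were collected for RNA extraction, and 5 µg of RNA entered rRNA depletion. The libraries came in 2 count tables. The first held 8 libraries: 3 of a tasA deletion, 3 of a cssRS deletion and 2 of wild type. Per the labels' protocols these were depleted of rRNA with Ribo-Zero, built with a directional kit and sequenced on a HiSeq 1500. The second held 5 libraries: 2 of a sipW deletion and 3 of wild type. Per the labels' protocols these were depleted with RiboMinus and built with a TruSeq kit, which does not keep the strand. Genotypes were taken from the sample titles and genotype labels. The series' design text calls the libraries of the first table biological replicates. For the second table nothing says that the samples came from separate cultures, so its p-values measure only the spread between these samples, which may be technical.

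The deposited values are raw read counts per gene, whole numbers that sum to a different total in each library. Per the submitters' processing notes, cutadapt, Bowtie2 2.3.4.1 and HTSeq were used. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. Reads of overlapping or antisense genes may therefore be shared in either table. The total count per library ran from 3093232 to 3324291 in the first table and from 1258719 to 2203718 in the second. No identifier in either table was recognised as rRNA or tRNA, and none was left out as such. The first table listed 4362 identifiers, 4156 of them gene symbols. The second listed 4468, of which 4426 were locus tags and 42 were symbols. The locus tags belong to another strain's annotation than the table of gene names used here (assembly ASM904v1, strain 168), and they were left as they stand. That table was used only for gene lengths and for which genes neighbour each other.

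Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were left out by filterByExpr with a minimum count of 10, which left 3993 and 3708 genes. Library sizes were scaled by TMM. A quasi-likelihood model of group means was fitted to all libraries of a table, so that the wild type with 2 libraries shared the estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called changed at an adjusted p under 0.05. Log2 fold changes are given with their standard errors, and levels as CPM, counts relative to the scaled library size, with the SD over libraries. Intervals for ratios of counts are exact Poisson intervals at 95%, which cover counting error only. The 3 contrasts of the first table and the contrast of the second were each made within 1 table, because the tables were made with different kits. The 243 identifiers found in both tables were also fitted in 1 model of 5 group means, which tested whether the effect of the tasA deletion differed from that of the sipW deletion. Before averaging, replicates were compared by a chi-square of their counts over genes with at least 20 counts. The chi-square per gene lay between 5.31 and 33.6 in the 11 pairs, above the value of about 1 that sampling noise gives, so no library was counted as a copy of another.

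The contrasts, 39 gene lists with 598 entries, the rule for naming genes and most alternatives were fixed before the data were examined. The lists covered cell states of a biofilm, stress responses, secondary metabolites and central metabolism. Of the 598 entries, 556 were tested. Lists were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. Counts of changed members are given over all genes tested and adjusted over the list alone. Genes named in the text are those of the tapA operon and cssRS, the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap and whose higher group had a mean of at least 20 counts, a preset set of markers, and the 4 members with the smallest p-values of each list past its test. Other genes named in the text were chosen after their values were seen. They are the further members of the fla/che operon and of other lists, the prophage genes and the symbols of the second table.

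The alternatives were relative log expression, upper quartile and total-count scaling, DESeq2 1.42.0, no filter and a stricter filter, a robust fit, a 2-fold threshold, fits of only the groups compared, the replicate number as a block, each replicate left out, and camera with an estimated correlation and fry. Where leaving out a library left a group with 1 sample, that sample was assumed to vary like the other groups. Overlap between comparisons that share the wild type was set against 100 simulations of unchanged groups. A correction for gene length, the removal of the identifier with the most counts, single wild-type libraries for the overlap, leaving out each replicate for the overlap, and DESeq2 and upper quartile scaling for single genes were added after seeing the data. So were 2 tests of the difference between the tasA and the sipW deletion that do not share a single spread. The first was limma's voom with 1 variance weight per table, and the second combined the standard errors of the separate edgeR fits, with Welch's degrees of freedom. On simulated counts with 200 changed genes per contrast, the test recovered 73.1% of 2-fold changes for the tasA deletion against wild type (3993 genes), 82.1% for the cssRS deletion against wild type, 89.6% for the tasA against the cssRS deletion, and 4.48% for the sipW deletion against wild type (3708 genes). At 4-fold the last of these was 63.6%. False calls made up 8 of 143, 8 of 160, 12 of 161 and 2 of 47 calls. Camera recovered both planted lists and called 0 of 37 others, but the simulated genes varied independently, so this does not show how often it calls lists whose genes vary together.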

Results

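RNA was sequenced from biofilm colonies of the soil bacterium Bacillus subtilis after 24 hours on MSgg, a minimal medium used to grow biofilms. The labels give the laboratory strain PY79. Libraries of the first table nevertheless held 0.995 to 1.43% of their counts on SPbeta, a prophage this strain is generally described as lacking. The series asks how the loss of TasA, the main fibre-forming protein of the biofilm matrix, changes the cells of a colony, above all those that swim. The first table held 3 libraries of a tasA deletion, 3 of a deletion of cssRS, which encodes a sensor kinase and a response regulator of secretion stress, and 2 of wild type, with 3093232 to 3324291 counts each. The second held 2 libraries of a deletion of sipW, which encodes the signal peptidase that processes TasA and TapA, and 3 of wild type. The sipW deletion libraries had 2084183 and 2203718 counts, more than the 1258719 to 1348046 of the wild-type libraries. In the first table, a first principal component with 61.2% of the variance placed the tasA deletion at -31.1 to -26.3, wild type at 6.39 and 6.75, and the cssRS deletion at 21.7 to 26.4.

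The deleted genes were read first. The tasA gene had 0, 29 and 2 counts in the 3 tasA deletion libraries, against 5445 and 5854 in wild type. That is a ratio of 575 (95% interval 405 to 846). The regulator gene cssR had 1 count in 1 of the 3 cssRS deletion libraries and 110 counts in each wild-type library, a ratio of 359.8 (63.9 to 14270). The kinase gene cssS kept 89, 81 and 84 counts there, against 498 and 571 in wild type, which is 6.88-fold lower (5.997 to 7.92). The genes tapA and sipW, which precede tasA in its operon, rose in the tasA deletion. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, tapA rose by 1.25 ± 0.14 (log2 ± SE, adjusted p = 3.0e-06) and sipW by 0.86 ± 0.14 (adjusted p = 0.00014). In the cssRS deletion, tasA stood at 946 ± 101 CPM (counts scaled to library size, mean ± SD) against 1851 ± 105 in wild type, a log2 change of -0.97 ± 0.29 (edgeR, adjusted p = 0.017). This call was not kept without cssRS deletion replicate 3 (adjusted p = 0.0522), wild type replicate 1 (0.08235) or wild type replicate 2 (0.110), nor by DESeq2 (0.650). The spread for tasA in these fits also took in the tasA deletion libraries, with their 0, 29 and 2 counts, which can widen its standard error. Per library, tasA stood at 834.5 to 1030 CPM in the cssRS deletion and at 1777 and 1925 CPM in wild type. The deletion of sipW was not checked here, since the files do not pair the identifiers of the second table with symbols.

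**Figure D1:**
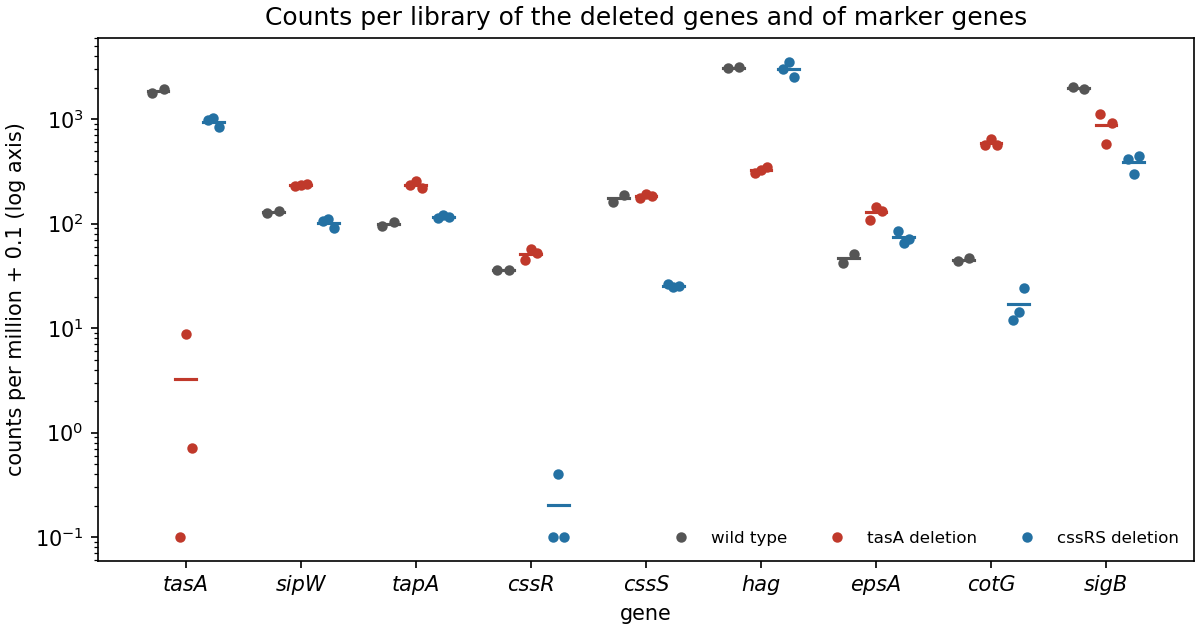
CPM of 9 genes in each of the 8 libraries of the first table, with 0.1 added, on a log axis; points are libraries and lines are group means. The tasA points of the tasA deletion and the cssR points of the cssRS deletion lie far below wild type, and hag stands at 325 CPM in the tasA deletion against 3116 in wild type.

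Colonies without TasA had less RNA for flagella, chemotaxis and the cell wall hydrolases made with them. The flagellin gene hag fell by 3.26 ± 0.15 (log2 ± SE, n = 3 against 2), from 3116 ± 83.1 to 325 ± 23 CPM (mean ± SD). The filament cap gene fliD changed by -2.25 ± 0.17, the motor gene motA by -2.58 ± 0.21 and the chemoreceptor gene mcpA by -2.77 ± 0.20. Their adjusted p-values by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 5.3e-10, 4.9e-08, 1.0e-07 and 4.0e-08. Of the 32 genes of the fla/che operon, which encodes the flagellar basal body and the chemotaxis proteins, 30 fell and 2 were not called, with 30 adjusted over the list alone and a median log2 change of -1.96. The members with the smallest p-values were cheA (-2.13 ± 0.16), fliK (-2.25 ± 0.18), flhA (-2.20 ± 0.18) and fliP (-2.30 ± 0.19). The operon's first genes did not move with the rest. The rod gene flgB changed by -0.03 ± 0.16 and flgC by -0.15, neither called, while fliE fell by 0.76. Near its end, sigD, the gene of the motility sigma factor, fell by 0.77 ± 0.22 (edgeR, adjusted p = 0.015), a call not kept without wild type replicate 1 (0.0614) or wild type replicate 2 (0.112). Of 26 other genes under SigD, 23 fell, or 25 adjusted over the list alone, with a median of -1.70. All 5 autolysin genes fell, also adjusted over the list alone, among them lytC (-2.25 ± 0.16), lytB (-2.16 ± 0.17) and lytA (-2.76 ± 0.30). The 3 lists passed camera with adjusted p = 3.1e-32, 1.3e-30 and 5.2e-10, and each had adjusted p = 0.0879 with an estimated correlation.

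**Figure D2:**
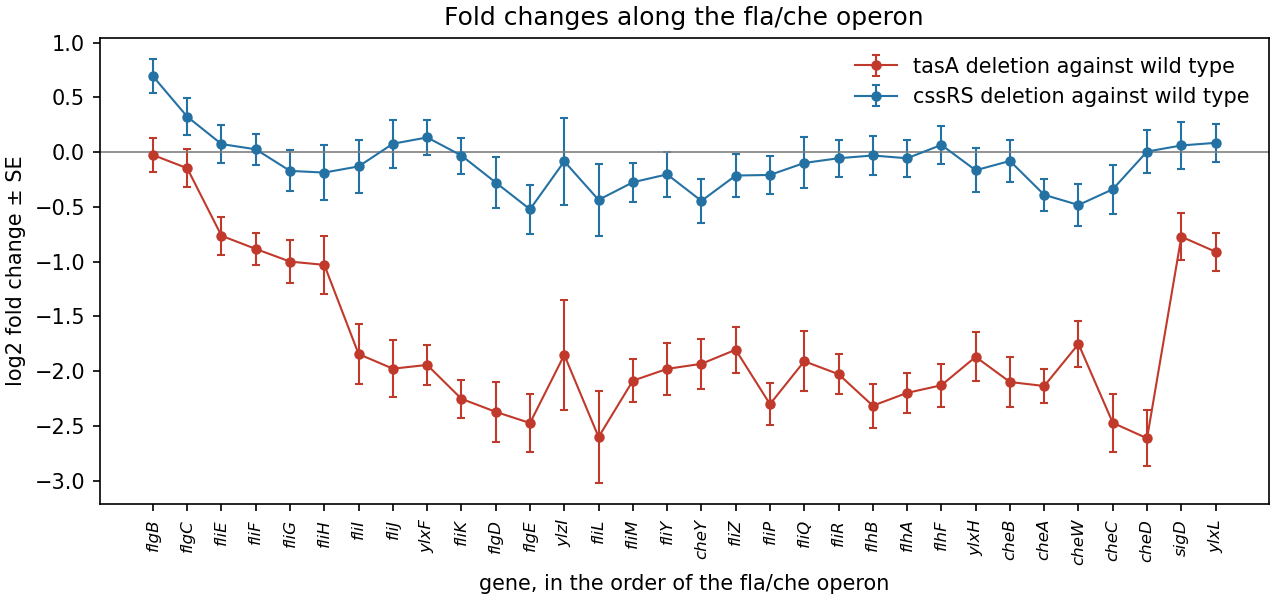
Log2 fold change ± SE against wild type of the 32 genes of the fla/che operon in operon order, in the tasA and the cssRS deletion. In the tasA deletion flgB lies at -0.03, fliK at -2.25, cheD at -2.61 and sigD at -0.77, and in the cssRS deletion 1 gene rose, 1 fell and 30 were not called.

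Matrix polysaccharide genes moved the other way in the same colonies. All 15 genes of the eps operon, which builds the exopolysaccharide of the matrix, rose, and all 15 did so adjusted over the list alone, with a median log2 change of 1.08. The first gene, epsA, rose by 1.46 ± 0.19 from 46.5 ± 6.73 to 128 ± 19.4 CPM, epsB by 1.12 ± 0.13 and epsN by 1.16 ± 0.19. The list passed camera with adjusted p = 8.0e-09, and had adjusted p = 0.217 with an estimated correlation. The regulator gene slrR, whose protein pairs with SinR to hold cells in the chained, matrix-making state, rose by 1.26 ± 0.24 (edgeR, adjusted p = 0.00084), whereas sinR (0.23 ± 0.13), sinI (0.04 ± 0.14) and abrB (0.26 ± 0.16) were not called. The gene bslA of the surface hydrophobin was not called either (-0.40 ± 0.16, edgeR, adjusted p = 0.087). Over its 19 genes with a known length, the list of biofilm and motility regulators was not called (camera, adjusted p = 0.993). After a correction for gene length 1 of these regulators rose and 3 fell. The list of the 4 matrix protein genes, which holds tasA itself, was not called (camera, adjusted p = 0.0904), and its median (0.23) and its test (down) differed in sign. Left-out libraries brought it past the threshold, with 0.0312, 0.00112 and 0.0353 without tasA deletion replicates 1, 2 and 3.

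Sporulation genes split by stage in the tasA deletion, with late genes higher and early forespore genes lower. Of 21 genes of the mother cell sigma factor SigK, which encode spore coat and crust proteins, 20 rose, also adjusted over the list alone, with a median log2 change of 3.02. The coat gene cotG rose by 3.71 ± 0.21, from 45.2 ± 2.56 to 591 ± 46.0 CPM, cotC by 3.83 ± 0.19 and the crust gene cgeA by 3.93 ± 0.23. The coat laccase gene cotA was the member not called (0.12 ± 0.20). Of 15 genes of the late forespore factor SigG, 8 rose and 7 were not called, with 9 up and 1 down adjusted over the list alone. The genes of the DNA-binding spore proteins rose most clearly, with sspE up by 2.03 ± 0.15, sspB by 2.28 ± 0.19 and sspA by 1.91 ± 0.17. Of 10 genes of the early forespore factor SigF, 8 fell and 1 rose, with 9 down and 1 up adjusted over the list alone, among them sigF itself (-1.15 ± 0.15) and bofC (-1.65 ± 0.18). The SigK, SigG and SigF lists passed camera with adjusted p = 6.2e-49, 3.2e-06 and 0.00023. With an estimated correlation they had adjusted p = 0.0879, adjusted p = 0.141 and adjusted p = 0.336, respectively. The SigE list of early mother cell genes was not called, with 3 of 23 up and 6 down, or 4 and 8 adjusted over the list alone.

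Respiration, nitrogen and antibiotic genes also changed in colonies without TasA. The nitrate reductase genes narG, narH, narJ and narI rose by 3.39 ± 0.35, 3.76 ± 0.32, 3.81 ± 0.38 and 4.26 ± 0.37 from wild-type levels of 1.31 to 2.62 CPM. Over the anaerobic list, 9 of 21 genes rose and 4 fell, or 12 and 4 adjusted over the list alone (camera, adjusted p = 0.0011, and adjusted p = 0.436 with an estimated correlation). The 4 that fell were the nitrite reductase genes nasD and nasE, nasF for the sirohaem cofactor and the flavohaemoglobin gene hmp. Nitrogen limitation genes fell, 10 of 12 with 1 up, the same numbers adjusted over the list alone. Among them the glutamine synthetase gene glnA changed by -1.80 ± 0.19, nasA by -2.02 ± 0.19 and the asparaginase gene ansZ by -2.30 ± 0.20 (list, camera, adjusted p = 1.2e-08, and adjusted p = 0.217 with an estimated correlation). All 9 genes for the bacteriocin subtilosin rose, also adjusted over the list alone, with albG up by 2.35 ± 0.17 and sboA by 1.36 ± 0.14 (camera, adjusted p = 1.4e-16, and adjusted p = 0.130 with an estimated correlation).

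General stress, protease and toxin genes were lower. The lists of heat shock, cell envelope stress and peroxide stress were not called. Over their genes with a known length they had camera's adjusted p = 0.464, 0.0759 and 0.817. Of 24 genes of the general stress factor SigB, 22 fell and 1 rose, also adjusted over the list alone, with katE at -1.38 ± 0.15, gspA at -1.28 ± 0.14 and the ribosome hibernation gene hpf the one that rose (camera, adjusted p = 3.8e-11, and adjusted p = 0.310 with an estimated correlation). Of 8 secreted protease genes 6 fell, with 6 down and 1 up adjusted over the list alone, among them vpr (-1.80 ± 0.15) and aprE (-1.22 ± 0.13), with camera's adjusted p = 3.5e-06, and adjusted p = 0.141 with an estimated correlation. All 6 bacilysin genes fell, also adjusted over the list alone, led by bacD (-1.05 ± 0.14), with camera's adjusted p = 0.00054, and adjusted p = 0.317 with an estimated correlation. Of 12 cannibalism toxin genes 7 fell, the same number adjusted over the list alone, led by skfB (-1.17 ± 0.15), with camera's adjusted p = 0.0063, and adjusted p = 0.317 with an estimated correlation. Of 4 pulcherriminic acid genes 3 fell, also adjusted over the list alone (camera, adjusted p = 0.0391, and adjusted p = 0.527 with an estimated correlation). The last call was not kept without tasA deletion replicate 1 (0.0606), tasA deletion replicate 3 (0.0858) or wild type replicate 1 (0.0577). Of 3 tested genes for poly-gamma-glutamate, the depolymerase gene pgdS fell by 2.10 ± 0.17, the 1 call also adjusted over the list alone, with camera's adjusted p = 0.0335, and adjusted p = 0.217 with an estimated correlation. Without tasA deletion replicate 3 the list had adjusted p = 0.05004.

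Over all genes, 904 of 3993 changed in the tasA deletion against wild type, 417 up and 487 down, and 447 of them by at least 2-fold. Beyond the lists, the largest rises included spoVIF (3.77 ± 0.21), a late sporulation gene, and yhcO and ymaG (3.99 ± 0.52 and 3.75 ± 0.33), and the largest falls the purine catabolism genes pucB and pucA (-3.40 ± 0.32 and -2.92 ± 0.30), yfmT (-2.82 ± 0.23) and ylqB (-2.88 ± 0.15). The count was 552 without wild type replicate 1 and 599 without wild type replicate 2. With total counts in place of TMM the median log2 change of all genes was 0.16, against 0.03 with TMM, and 577 genes were up and 365 down.

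**Figure D3:**
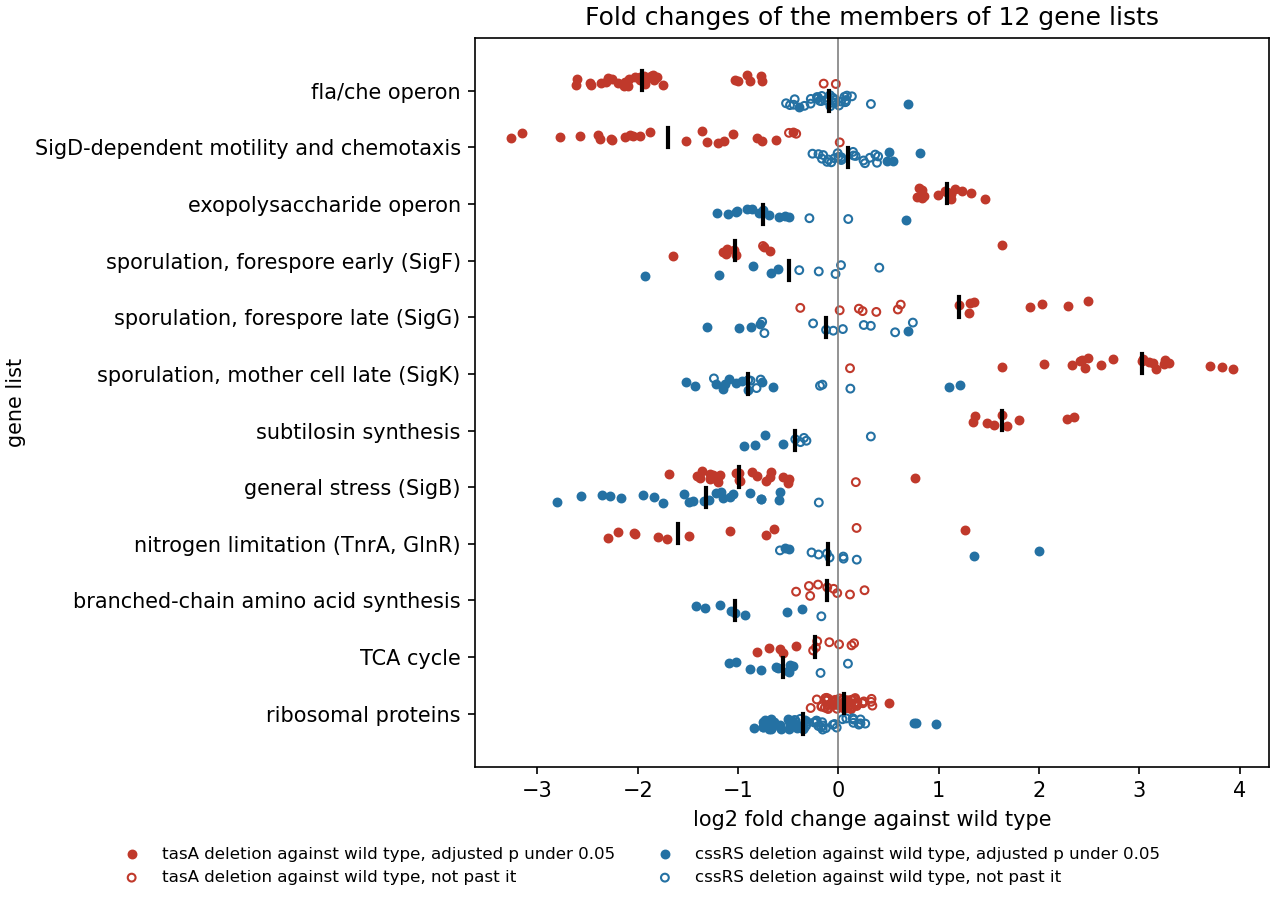
Log2 fold changes against wild type of the members of 12 gene lists in the tasA and the cssRS deletion; filled points are genes with an adjusted p under 0.05, open points are the others, and black lines are list medians. In the tasA deletion the SigK list has its median at 3.02 and the fla/che operon at -1.96, and in the cssRS deletion the SigB list has its median at -1.32.

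Colonies without CssRS had less RNA for general stress, branched-chain amino acid synthesis and central metabolism, and no motility list was called. The flagellin gene hag changed by -0.04 ± 0.14 and was not called, at 3032 ± 510 CPM against 3116 ± 83.1. For the 3 motility lists camera's adjusted p was 0.781 for fla/che, 0.211 for the other SigD genes and 0.164 for autolysins. After a correction for gene length, 3 of the 26 other SigD genes and 2 of 5 autolysin genes rose and 0 fell. Of 32 fla/che genes 1 then rose and 2 fell. Of 24 SigB genes 23 fell, also adjusted over the list alone, with a median log2 change of -1.32. The sigma factor gene sigB changed by -2.35 ± 0.21, from 1975 ± 72.4 to 387 ± 75.4 CPM, and the catalase gene katE by -2.17 ± 0.15 (edgeR, adjusted p = 1.0e-06 and 1.2e-07). Of 9 genes for valine, leucine and isoleucine 8 fell, also adjusted over the list alone, among them leuC (-1.42 ± 0.12) and leuB (-1.33 ± 0.13). The SigB and branched-chain lists passed camera with adjusted p = 3.5e-27 and 2.3e-07, and both had adjusted p = 0.291 with an estimated correlation.

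The known targets of CssRS went different ways. The quality-control protease gene htrB rose by 0.57 ± 0.13 and htrA fell by 0.48 ± 0.13 (edgeR, adjusted p = 0.0025 and 0.0089), and ykoJ changed by -0.02 ± 0.19. The htrB call was not kept without wild type replicate 1 (0.0591), nor the htrA call without wild type replicate 1 (0.0696) or 2 (0.0701). With total counts htrA had a log2 change of -0.31 (edgeR, adjusted p = 0.0866), and with the trend with gene length removed -0.31 (edgeR, adjusted p = 0.0838). Of 5 genes of the CssRS list 3 fell and 1 rose, also adjusted over the list alone, with camera's adjusted p = 5.7e-05, and adjusted p = 0.291 with an estimated correlation. Of the 3 that fell, cssR and cssS are the deleted genes.

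Genes of the matrix polysaccharide and of the antibiotics plipastatin and bacillaene were lower without CssRS. Of 15 eps genes 12 fell and 1 rose, or 13 and 1 adjusted over the list alone, with epsO at -0.86 ± 0.15 and epsN at -0.91 ± 0.20. The one that rose was the first, epsA (0.67 ± 0.19, edgeR, adjusted p = 0.0104), a call not kept without wild type replicate 1 (0.148). Along the eps operon the mean log2 change went from -0.12 in the first of 3 parts to -0.91 in the last. The eps list had camera's adjusted p = 0.00486, and adjusted p = 0.582 with an estimated correlation. The hydrophobin gene bslA fell by 0.94 ± 0.16 (edgeR, adjusted p = 0.00035). Among 23 regulators of biofilm and motility 9 rose and 14 were not called, or 10 up adjusted over the list alone, with sinR up by 0.66 ± 0.13, sinI by 0.65 ± 0.14 and slrA by 1.10 ± 0.22. This was the only one of the 20 called lists that rose (camera, adjusted p = 0.00486, and adjusted p = 0.569 with an estimated correlation). All 5 plipastatin genes fell, also adjusted over the list alone, with ppsB at -1.02 ± 0.14, camera's adjusted p = 0.00094, and adjusted p = 0.582 with an estimated correlation. Of 15 bacillaene genes 11 fell and 1 rose, or 12 and 1 adjusted over the list alone, with pksJ at -1.14 ± 0.15, camera's adjusted p = 0.00013, and adjusted p = 0.310 with an estimated correlation. The plipastatin genes and some, but not all, of the bacillaene genes are among the longest of the chromosome. Fold changes in this contrast fell with gene length, with a median of 0.21 for genes of up to 450 coding bases and -0.17 for those of at least 1176. With the length trend removed, plipastatin had adjusted p = 0.235 and bacillaene adjusted p = 0.0509. The eps and the regulator lists then had camera's adjusted p = 0.0509 as well. Over genes with a known length the eps median went from -0.68 to -0.55 and the regulator median from 0.35 to 0.15. The gene sinI then had a log2 change of 0.28 (edgeR, adjusted p = 0.148). The lists of matrix proteins, surfactin and bacilysin were not called (camera, adjusted p = 0.164, 0.209 and 0.0508). Bacilysin had 0.01305 without cssRS deletion replicate 3 and 0.0260 without wild type replicate 2.

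Genes of the TCA cycle, ATP synthase, ribosomal proteins, phosphate starvation and anaerobic growth fell as well. Of 12 TCA cycle genes 10 fell, also adjusted over the list alone, with sucD at -1.02 ± 0.13 and mdh at -0.88 ± 0.14 (camera, adjusted p = 0.00034, and adjusted p = 0.582 with an estimated correlation). Of 9 ATP synthase genes 7 fell, also adjusted over the list alone, with atpD at -0.73 ± 0.13 (camera, adjusted p = 0.0066, and adjusted p = 0.582 with an estimated correlation). Of 58 ribosomal protein genes 26 fell and 3 rose, or 30 and 3 adjusted over the list alone, with a median of -0.35 (camera, adjusted p = 0.0045, and adjusted p = 0.584 with an estimated correlation). Of 17 phosphate starvation genes 9 fell, or 10 adjusted over the list alone, with pstS at -1.67 ± 0.24 and tuaB at -1.82 ± 0.22 (camera, adjusted p = 0.00096, and adjusted p = 0.582 with an estimated correlation). Of 21 anaerobic genes 12 fell, also adjusted over the list alone, with hmp at -1.68 ± 0.17 (camera, adjusted p = 0.00486, and adjusted p = 0.582 with an estimated correlation).

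Further stress and nutrient lists and the subtilosin list also passed the test without CssRS. Of 15 heat shock genes 9 fell, or 9 down and 1 up adjusted over the list alone, with the chaperone gene dnaK at -0.72 ± 0.13 (camera, adjusted p = 0.00635, and adjusted p = 0.582 with an estimated correlation). Of 25 genes of iron uptake 8 fell and 1 rose, or 9 and 1 adjusted over the list alone, with dhbB of the siderophore bacillibactin at -1.11 ± 0.15 (camera, adjusted p = 0.0176, and adjusted p = 0.310 with an estimated correlation). With the length trend removed, the iron list had adjusted p = 0.0509 and the anaerobic list adjusted p = 0.0835, while their medians over the 15 and 19 genes with a known length went from -0.42 to -0.37 and from -0.43 to -0.44. The median of all 25 iron genes was -0.22. The lists of cell envelope stress (11 down and 2 up of 28), histidine synthesis (6 down of 8), subtilosin (4 down of 9) and peroxide stress (7 down and 1 up of 12) had camera's adjusted p = 0.0222, 0.0227, 0.0392 and 0.0493. Adjusted over the list alone they had 13 down and 2 up, 8 down, 5 down and 1 up, and 8 down and 1 up. With an estimated correlation envelope stress and peroxide stress had adjusted p = 0.582, histidine synthesis adjusted p = 0.5845 and subtilosin adjusted p = 0.591. Envelope stress was not called without cssRS deletion replicate 2 (0.0542) or wild type replicate 1 (0.0597), nor histidine synthesis without cssRS deletion replicate 3 (0.0753) or wild type replicate 2 (0.0681). Subtilosin was not called without cssRS deletion replicate 1 (0.1495), cssRS deletion replicate 2 (0.0542) or wild type replicate 1 (0.133). Peroxide stress was not called without cssRS deletion replicates 1 (0.0983) or 2 (0.0648) or wild type replicates 1 (0.0597) or 2 (0.0595), and its catalase gene katA fell by 1.29 ± 0.15. Over the 23 and 11 genes with a known length, envelope and peroxide stress were not called (camera, adjusted p = 0.0847 and 0.0833), nor with the length trend removed (0.0595 and 0.125), while their medians went from -0.35 to -0.32 and from -0.48 to -0.43.

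Late mother cell genes and early forespore genes of sporulation were lower without CssRS. Of 21 SigK genes 11 fell and 2 rose, or 13 and 2 adjusted over the list alone, with cotG at -1.43 ± 0.22 and cotZ at -1.51 ± 0.24 (camera, adjusted p = 0.00486, and adjusted p = 0.582 with an estimated correlation). Of 10 SigF genes 5 fell, or 6 adjusted over the list alone, with bofC at -1.93 ± 0.19 (camera, adjusted p = 0.0127, and adjusted p = 0.582 with an estimated correlation). The SigF list was not called without cssRS deletion replicate 2 (0.0645) or wild type replicate 1 (0.0544). The late forespore SigG list was not called, with 4 of 15 down and 1 up, also adjusted over the list alone (camera, adjusted p = 0.281). Over all genes, 1374 of 3993 changed, 646 up and 728 down, and 359 by at least 2-fold. The largest rises included yuzO (2.60 ± 0.17), the nitrogen regulator gene tnrA (2.00 ± 0.19) and its neighbour ykzB (1.99 ± 0.18), and the largest falls the transporter gene ywtG (-3.47 ± 0.25), yqxL (-2.84 ± 0.22), yfkE (-2.84 ± 0.27) and csbC (-2.81 ± 0.26). The count was 694 without wild type replicate 1 and 823 without wild type replicate 2. With total counts in place of TMM the median log2 change of all genes was 0.16, against -0.02 with TMM, and 948 genes were up and 468 down.

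Against wild type, some genes fell in both the tasA and the cssRS deletion, among them katE (-1.38 ± 0.15 and -2.17 ± 0.15) and bofC (-1.65 ± 0.18 and -1.93 ± 0.19). In all 240 genes fell in both (edgeR, adjusted p under 0.05), where independent lists would share 88.8, and 70 rose in both, where 67.5 would. In opposite directions 66 genes rose without TasA and fell without CssRS (76.0 for independent lists), and 25 did the reverse (78.8). Both comparisons used the same 2 wild-type libraries, and unchanged groups simulated against them shared 0 to 2 calls of the same direction over 100 simulations. No gene was changed in those simulations, so they do not show how many calls the shared controls add where many genes change. The covariance of the log2 fold changes across genes was 0.0897, against 0.0367 in the simulations, a difference of 0.053. Pearson's r was 0.186 and Spearman's rho 0.300, against 0.612 and 0.579 in simulated unchanged groups, and genes are not independent replicates. The wild type could not be split into parts of at least 2 libraries, so part of the excess may come from the shared controls. In total 310 calls were shared in direction. Pearson's r was 0.113 without tasA deletion replicate 2 and 0.282 without wild type replicate 2. With a different wild-type library for each deletion, and so no shared control, the covariance was 0.0636 and 0.074. Pearson's r was then 0.116 and 0.137.

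Set against each other without the wild type, the deletions differed in motility, matrix, sporulation and energy genes. All 32 fla/che genes, 24 of 26 other SigD genes and all 5 autolysin genes were lower in the tasA than in the cssRS deletion, each number unchanged adjusted over the list alone, with hag at -3.22 ± 0.14 (edgeR, adjusted p = 3.3e-11). These lists had camera's adjusted p = 1.1e-20, 4.2e-25 and 9.3e-10. With an estimated correlation fla/che had adjusted p = 0.144 and the others adjusted p = 0.120. All 15 eps genes were higher, also adjusted over the list alone, with epsN at 2.07 ± 0.18 (camera, adjusted p = 3.7e-13, and adjusted p = 0.149 with an estimated correlation). Of 21 SigK genes 20 were higher, also adjusted over the list alone, with a median of 3.83 and cotG at 5.14 ± 0.20 (camera, adjusted p = 1.7e-47, and adjusted p = 0.0857 with an estimated correlation). Of 15 SigG genes 8 were higher, also adjusted over the list alone, with sspB at 3.59 ± 0.18 (camera, adjusted p = 1.8e-06, and adjusted p = 0.131 with an estimated correlation). All 9 subtilosin genes were higher, also adjusted over the list alone, with albA at 2.62 ± 0.17 (camera, adjusted p = 4.4e-18, and adjusted p = 0.120 with an estimated correlation).

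Nitrogen genes were lower in the tasA than in the cssRS deletion, 9 of 12 with 2 higher, the same adjusted over the list alone, with tnrA at -3.08 ± 0.18 and ansZ at -2.35 ± 0.19 (camera, adjusted p = 1.5e-07, and adjusted p = 0.273 with an estimated correlation). Anaerobic genes were higher, 17 of 21 with 2 lower, or 18 and 2 adjusted over the list alone, with narG at 4.61 ± 0.35 (camera, adjusted p = 8.2e-08, and adjusted p = 0.263 with an estimated correlation). Of 9 ATP synthase genes 8 were higher, also adjusted over the list alone (camera, adjusted p = 0.0069, and adjusted p = 0.466 with an estimated correlation). Of 9 branched-chain genes 7 were higher, also adjusted over the list alone, with leuC at 1.13 ± 0.11 (camera, adjusted p = 0.00053, and adjusted p = 0.274 with an estimated correlation). Of 58 ribosomal protein genes 34 were higher and 3 lower, or 36 and 3 adjusted over the list alone (camera, adjusted p = 0.0069, and adjusted p = 0.717 with an estimated correlation). Of 24 SigB genes 13 were higher and 2 lower, or 14 and 2 adjusted over the list alone, with hpf at 1.54 ± 0.12 (camera, adjusted p = 0.0089, and adjusted p = 0.751 with an estimated correlation). The SigB call was not kept without tasA deletion replicate 1 (0.0572). Of 17 phosphate starvation genes 10 were higher, also adjusted over the list alone, with pstS at 1.54 ± 0.22 (camera, adjusted p = 0.0155, and adjusted p = 0.635 with an estimated correlation). Of 8 secreted protease genes 5 were lower, also adjusted over the list alone, with vpr at -1.25 ± 0.13 and epr at -1.59 ± 0.15 (camera, adjusted p = 0.0227, and adjusted p = 0.418 with an estimated correlation). Of 23 regulators 14 were lower and 2 higher, or 15 and 2 adjusted over the list alone, with the motility regulator gene swrAA at -1.62 ± 0.23 (camera, adjusted p = 0.0155, and adjusted p = 0.3745 with an estimated correlation). Over the 19 regulators with a known length the list was not called (camera, adjusted p = 0.0594), nor with the length trend removed (0.106), while the median went from -0.37 to -0.40. The CssRS list, with 2 of 5 genes higher and 1 lower, or 2 and 2 adjusted over the list alone, holds the deleted genes (camera, adjusted p = 0.0094, and adjusted p = 0.274 with an estimated correlation). Over all genes 1830 of 3993 differed, 934 higher and 896 lower in the tasA deletion, 575 of them by at least 2-fold.

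In the second table, colonies without SipW had less RNA from 5 of the genes with a symbol and more from 1, a gene of the subtilosin operon. Of 19 tested symbols 1 rose and 5 fell. The subtilosin operon gene sboX rose by 1.65 ± 0.36, from 172 ± 77.6 to 542 ± 47.9 CPM (mean ± SD, n = 2 against 3). It overlaps sboA, and how the counting treated such reads is not given in the sources used here. The genes ywzE, rgpA, ypzG and phrI changed by -2.88 ± 0.38, -2.70 ± 0.48, -3.10 ± 0.70 and -1.41 ± 0.41, of which phrI encodes a signalling peptide. The other that fell, usd, which precedes the sporulation gene spoIIID, had 2 and 0 counts in the sipW deletion and 23, 104 and 86 in wild type. The adjusted p-values of the 6 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment lay between 0.0135 and 0.0455. The coat genes cotG (0.62 ± 0.61) and cotD (0.09 ± 0.28) were not called. The files do not pair the other identifiers with symbols. Among them, BS3610_RS20905 and BS3610_RS20910 rose from 6.11 ± 3.77 to 114 ± 3.77 and from 16.4 ± 8.70 to 243 ± 29.9 CPM (edgeR, adjusted p = 0.0135 for both), and BS3610_RS18620 and BS3610_RS13565 fell to 0 counts in both sipW deletion libraries, from means of 20.3 ± 18.8 and 18.3 ± 13.8 CPM. In all, 812 of 3708 identifiers changed, 286 up and 526 down, and 666 by at least 2-fold. By edgeR no identifier was called without sipW deletion replicate 2 (818 had an unadjusted p under 0.05) or without wild type replicate 3 (1204), 31 were called without sipW deletion replicate 1, and 1428 without wild type replicate 1, and DESeq2 called 1007 on all 5 libraries. Wild type replicate 1 lay at 4.03 on a first principal component with 77.3% of the variance, wild type replicates 2 and 3 at 45.2 and 35.7, and the sipW deletion at -39.9 and -45.0. With total counts in place of TMM the median log2 change of all identifiers was -0.16, and 159 were up and 660 down.

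Effects of the tasA and the sipW deletion were compared on the 243 identifiers of both tables, each deletion against its own wild type. These are a small part of the 4362 identifiers of the first table, and most are locus tags without a symbol. The flagellar and eps genes were not among those tested, so the comparison does not cover the whole genome. Of 128 tested in both tables, 2 rose in both, where independent lists would share 0.266, and 0 fell in both, where 0.172 would. In opposite directions 2 rose without TasA and fell without SipW (1.46 for independent lists), and 0 did the reverse (0.0313). Pearson's r of the changes was -0.09 and Spearman's rho 0.102, and genes are not independent replicates. At an adjusted p under 0.05, 30 of the 201 identifiers tested in 1 fit of both tables differed in the test of the difference itself, 29 of them with the higher change in the tasA deletion. The spore coat gene cotG changed by 3.71 in the tasA and 0.62 in the sipW deletion, and the spore protein gene sscA by 3.47 and -0.83 (edgeR, adjusted p of the differences = 3.8e-06 and 1.0e-09). The count was 19 without sipW deletion replicate 2. This fit shares a single spread, though the biological coefficient of variation was 12.6% in the first table and 28.5% in the second, so its standard errors can be too small for the sipW deletion. The standard error of the cotG difference was 0.51 in this fit and 0.64 from the separate fits of each table. In 2 tests chosen after seeing the data, 26 of 201 identifiers differed with a variance weight for each table (limma), with adjusted p = 6.3e-05 for cotG and 6.1e-08 for sscA, and 21 of 128 with the standard errors of the separate fits. Kit, sequencer and strand differ between the tables. Their effects cancel where they are common to a deletion and its own wild type, but would remain in a difference where they are not.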

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

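The joint test of each difference between the deletions was fixed before the data were examined, and the genes named were those with a symbol among the identifiers that passed it. For 30 of the 201 identifiers tested in 1 fit of both tables, the change against wild type differed between the tasA and the sipW deletion (edgeR, adjusted p under 0.05), 29 with the higher value in the tasA deletion. Of 13 with a symbol, 3 are genes of the spore: the difference of log2 changes was 4.30 ± 0.51 for sscA, 3.08 ± 0.51 for cotG and 1.54 ± 0.42 for cotD. Behind these lie changes of 3.47 and -0.83 for sscA, 3.71 and 0.62 for cotG, and 1.63 and 0.09 for cotD, in the tasA and the sipW deletion. The difference was 4.64 for ypzG, 3.63 for rgpA and 2.75 for ywzE, and ypzG had changes of 1.53 and -3.11. For rgpA the changes were 0.93 and -2.70, and for ywzE -0.14 and -2.89, of which only those in the sipW deletion were called. It was 8.45 for usd and 11.97 for yezF, fitted values that depend on the prior count, since usd had 2 and 0 counts in the sipW deletion and yezF had 0 in both of its libraries. It was 2.49 for yczM, 2.28 for yvzI, 1.499 for yoyJ and 3.52 for yozZ. The changes of yvzI (0.74 and -1.54) and yoyJ (0.39 and -1.11) were also called only in the sipW deletion. For yezG the difference was -1.14, the 1 identifier with the lower value in the tasA deletion. The joint fit shares a single spread, though the biological coefficient of variation was 12.6% in the first table and 28.5% in the second, so its standard errors can be too small for the sipW deletion. From separate fits of each table the differences were 4.29 ± 0.61 for sscA, 3.08 ± 0.64 for cotG and 1.54 ± 0.36 for cotD. Of 2 tests chosen after seeing the data, 1 with a variance weight for each table called 26 of 201 identifiers (limma, adjusted p = 6.1e-08 for sscA, 6.3e-05 for cotG and 0.0103 for cotD), and 1 with the standard errors of the separate fits called 21 of 128. Neither called yoyJ (limma, adjusted p = 0.0725) or yvzI (0.148), and the second did not test yezF and yozZ. The tables differ in rRNA depletion, library kit, strand and sequencer, and no library of 1 deletion was made in the other way. A technical effect common to a deletion and its own wild type cancels from the difference. One that acts on them differently would stay in it and cannot be told apart from an effect of the deletions.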

How the results depend on the processing

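The length correction, single wild-type libraries and left-out replicates for the overlap, the removal of the identifier with the most counts, DESeq2 and upper quartile scaling for single genes, and the difference between the tasA and sipW deletions with a spread for each table were chosen after seeing the data. Over 455 results and 5735 alternative values, single genes kept their direction and side of the threshold in 4099, lost their call in 155, gained one in 11 and reversed in 1, and lists did so in 1193, 85, 42 and 0. The reversed one was srfAA in the cssRS deletion, at 0.063 with the length correction, and the cause was not tested. With an estimated inter-gene correlation camera called 0 lists in each of the 3 contrasts, against 16, 20 and 17 with the preset one, with 8, 5 and 7 lists at an unadjusted p under 0.05, and fry called 21, 22 and 26. Over genes with a known length, 17 lists fell and 1 rose in the cssRS deletion before the length correction, and 12 were called after it. A 2-fold minimum left 447, 359 and 575 genes. Leaving out 1 replicate gave 552 to 835 genes for the tasA deletion against wild type, 694 to 1390 for the cssRS deletion against wild type, 1456 to 1845 between them and 0 to 1428 for the sipW deletion (edgeR). At an unadjusted p under 0.05 the settings with 0 had 818 and 1204. It gave 19 to 35 identifiers that differed between the tasA and sipW deletions, against 30 with all libraries, 26 with a variance weight per table (limma) and 21 with the standard errors of separate fits, and 130 to 319 genes shared in direction by the tasA and cssRS deletions. With a different wild-type library for each deletion the shared genes were 112 and 143, and fewer libraries entered each fit. Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated by -0.0571 to 0.169 in the first table and by -0.154 and -0.14 in the second. With the replicate number as a block, the sipW deletion had 0 genes by title numbers (964 at an unadjusted p under 0.05) and 430 by library code numbers, and DESeq2 without the block had 1007. For the first table the title block gave 895, 1419 and 1868 genes and the code block 737, 1255 and 1586. No called list's median changed sign under relative log expression, upper quartile or total-count scaling. Medians near 0 of lists not called did, among them iron uptake in the tasA deletion (-0.06, and 0.07 with total counts) and fla/che and SigG in the cssRS deletion (-0.09 and -0.12, and 0.08 and 0.05 with total counts). For the sipW deletion 4.48% of simulated 2-fold changes were recovered, against 73.1% for the tasA deletion. The second table had fewer counts per library and a biological coefficient of variation of 28.5% against 12.6%, and their parts in this were not separated.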

Other observations

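The tests of operon position, gene length, prophage reads and splits below were chosen only after the results were seen. Competence and purine genes went both ways without CssRS. The competence regulator gene comK fell by 1.53 ± 0.23 and the DNA processing gene dprA by 0.74, while the uptake genes comFB and comEB rose by 0.74 and 0.68 (edgeR, adjusted p = 0.00014, 0.0044, 0.0146 and 0.0226). Over the competence list 3 of 11 rose and 2 fell, or 4 and 2 adjusted over the list alone, and camera did not call it (adjusted p = 0.680). In purine synthesis purE rose by 1.31 and purS fell by 0.67 (edgeR, adjusted p = 0.0062 and 0.0134), with 2 of 12 up and 3 down and no call by camera (adjusted p = 0.313). The PBSX prophage list had camera's adjusted p = 0.863 in the tasA and 0.891 in the cssRS deletion.

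In the tasA deletion the fla/che operon fell least in its first genes, with a mean log2 change of -1.19 in the first of 3 parts of the operon, -2.14 in the middle and -1.89 in the last, a difference of -0.71 between last and first. If the libraries held fewer reads from downstream genes of long operons, other long operons would fall along their length too. The median difference of 13 other operons was -0.1185, with a range of -0.44 to 0.90. Gene length was argued against by the fla/che difference after a length correction, which was -0.6887. Of the 13 operons, 7 fell along their length and 4 reached 0.25 of the fla/che value. The 13 had 5 to 15 genes against 32 in fla/che, so their median cannot decide about a longer operon. A part from read position stays open. A candidate biological explanation, a change in transcription or decay within the operon in cells without TasA, was not tested. In the cssRS deletion 8 of the 13 other operons fell along their length, with differences from -1.26 to 1.59. The difference was -1.26 for pyr, -0.82 for pur, -0.79 for eps and -0.64 for atp, but 1.59 for tua and 0.73 for pst. After the length correction these were -1.28, -0.78, -0.89, -0.46, 1.01 and 0.69. Their cause was not tested.

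Fold changes of the cssRS deletion fell with gene length, with a Spearman correlation across genes of -0.252, and genes are not independent replicates. Of 17 lists that fell over their genes with a known length, 12 stayed past the threshold after the trend was removed and kept a median of 96.51% of their fall, though they were chosen by having stayed. The SigB list went from -1.31 to -1.37. Bacillaene and plipastatin synthesis kept at most 40.83%, going from -0.90 to -0.31 and from -0.87 to -0.35. The trend was fitted to these genes too, and the longest of them lie at its far end. The smaller falls therefore cannot tell gene length from a real fall of these lists. Per library, relative to the wild-type mean, the correlation was -0.225 to -0.258 in the cssRS deletion, -0.172 to -0.0322 in the tasA deletion and 0.11 and -0.11 in wild type, and whether the trend comes from the RNA of the libraries or from the cells stays open.

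Libraries labelled PY79, a strain generally described as lacking the SPbeta prophage, held counts on SPbeta genes, 0.995 to 1.43% of each library of the first table. The small RNA gene bsrG and sunI were among the most abundant. Cells of a prophage-carrying strain with an intact tasA gene were considered as a source in the tasA deletion. The prophage share there was 120% of that in wild type and the tasA counts 0.174%. These percentages cannot decide it, since the same admixture in every library would give a similar prophage share in both groups. The prophage share itself was 1.15 to 1.24% of the counts in the tasA deletion libraries. That argues against such cells if they made tasA as wild type does, since they would then give about 0.174% of all counts. Reads of other genes counted on a few prophage genes stay open in part. At least 20 counts in every library were found for 39.1% of 156 prophage identifiers, against 76.53% of the others. The 10 most abundant held 66.59% of the prophage counts, less than the 90% that a few genes taking nearly all would give. Of 105 prophage genes tested, 34 rose and 0 fell in the cssRS deletion (edgeR, adjusted p under 0.05), against 646 and 728 of all 3993 genes. In the tasA deletion 13 rose and 3 fell, against 417 and 487. A strain background that carries the prophage was not tested.

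Splitting the 6 libraries of the tasA and cssRS deletions in other ways makes 10 splits, too few for a share under 0.05. In 1 of the 10, the real one, 1830 genes were called. The highest of the other splits had 0 (edgeR, 17 to 209 genes at an unadjusted p under 0.05). For gene lists (camera with the preset correlation), 5 splits had at least the 17 of the real one, and the highest other had 23. Each other split mixed libraries of both deletions in both of its groups. This widens the spread within groups and keeps part of the real difference, so neither the genes nor the lists of those splits measure chance.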
